A study of Mus musculus with 9 samples.

How the data were processed

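Bulk RNA was sequenced from the prelimbic cortex of 9 mice in 3 groups of 3, as given in the report. Per the labels, RNA was extracted with TRIzol and a column kit and libraries were sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 2.0.5 for alignment to mm10 and featureCounts 1.5.0-p3 for counting. The deposited table holds expected counts (estimated read counts per gene), whole numbers without normalization by the authors, for 55335 gene symbols in 9 libraries. The name of the deposited table gives StringTie instead of featureCounts. Whether reads were counted by strand or by pair is not given in the sources used here. Totals ran from 53624337 to 73586375 counts per library.

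The counts were read as given, and 20334 symbols had 0 counts in every library. 107 symbols occurred more than once, in 216 lines, which were kept apart. 27 symbols had been turned into dates by spreadsheet software and were left as they stood. Symbols were matched to GENCODE M21 on GRCm38, which gave an identifier to 21323 of the tested genes (98.0%). The 37 mitochondrial genes read 0 in all 9 libraries, while Gm28437, Gm28661, Gm29216 and Gm10925, nuclear pseudogenes of mitochondrial genes on chromosome 1, took 0.974% to 1.29% of the counts, so mitochondrially encoded genes were left out.

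Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 21765 genes with 99.96% of the counts, scaled by TMM (factors 0.979 to 1.03) and fitted with the robust quasi-likelihood model over all 9 libraries, with 1 mean per group. The common biological coefficient of variation was 0.203. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. With 3 mice against 3, an exact permutation test on a single gene could not go below 0.1, so the tests rest on the spread shared across genes. CPM use the TMM-scaled library sizes. The comparisons were injured saline against sham, R-HNK against injured saline, R-HNK against sham, and any difference among the 3 groups. A gene counted as reversed when it passed in the first 2 comparisons with opposite signs.

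In all, 31 lists of genes were tested, 17 of pathways and 14 of cell type markers, with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and adjustment over the 31 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Adjusted over the list alone means that the edgeR p of the members was adjusted within the list. Genes were named by a rule: per comparison, up to 10 genes per direction with the largest fold change among those that passed with a mean log2 CPM of at least 0, a full gene symbol and no overlap between groups, filled to 5 by unadjusted p; up to 4 members of each list with the smallest p; up to 10 reversed genes with the largest smaller change; and Gria1, Gria2, Gria3, Gria4 and Dlg4. A full gene symbol here leaves out predicted genes and genes annotated as pseudogenes. The groups, comparisons, tests, lists, naming rule and first set of other settings were fixed before the data were examined.

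The first set of other settings was scaling by relative log expression or upper quartile, no filter, DESeq2 1.42.0, limma-voom with quality weights, replicate number as a block, the 2 compared groups alone, and leaving out each library in turn. Added after seeing the data were a filter at a mean log2 CPM of 0, halved counts, the striatal marker score as a covariate, and leaving out the 4 libraries raised in striatal markers. The analysis was tested on simulated negative binomial counts with the means and spread of these libraries and known changes, 3 simulations per comparison. For injured saline against sham mice it recovered 46.8%, 73.1% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 6.11% false calls. The shares were 50.7%, 70.6% and 94.9% with 5.26% false calls for R-HNK against injured saline mice, and 48.3%, 72.1% and 94.9% with 8.70% for R-HNK against sham mice. The known changes were placed in genes with a mean log2 CPM above 0 that are in no list. For genes with lower counts the shares were not measured. Genes were drawn independently, so tissue differences shared by many genes are not in these shares. Alignment, strand, splicing and sequence variants were not analysed here.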

Results

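RNA was sequenced from the prelimbic cortex, a medial prefrontal area that takes part in the control of pain and emotion, of 9 mice on day 14 after surgery. The mice formed 3 groups of 3: sham-operated mice given saline (sham mice), mice with spared nerve injury (SNI) given saline (injured saline mice), and mice with spared nerve injury given the ketamine metabolite hydroxynorketamine in its R form, R-HNK, at 10 mg/kg (R-HNK mice). Spared nerve injury severs some branches of the sciatic nerve and leaves another intact, and is a standard model of neuropathic pain. Each library came from a separate mouse, so n = 3 per group throughout. The deposited counts summed to 58654404, 57013333 and 53624337 in sham replicates 1, 2 and 3. They summed to 58755461, 60707528 and 65688561 in the injured saline replicates and 73586375, 64874399 and 62909267 in the R-HNK replicates. Levels are given as CPM, each gene's count scaled to a common library total by edgeR's cpm function, as mean ± SD over 3 mice. Fold changes are on the log2 scale with a standard error (SE) worked back from edgeR's test statistic. The p also depends on degrees of freedom that differ between genes, so the SE alone does not show whether a gene passes.

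The libraries differed in markers of striatal medium spiny neurons, cells that lie outside the cortex. Drd2, the dopamine D2 receptor of these neurons, measured 1.23, 44.0 and 41.8 CPM in sham replicates 1, 2 and 3, 1.5, 1.72 and 1.55 CPM in the injured saline replicates, and 17.5, 1.27 and 24.6 CPM in the R-HNK replicates. Adora2a, an adenosine receptor of the same cells, gave 1.88, 62.6 and 69.2, then 2.57, 1.45 and 2.55, then 23.0, 2.04 and 40.6 CPM in the same order. Both genes were thus raised in 4 libraries, sham replicates 2 and 3 and R-HNK replicates 1 and 3, and in no injured saline library. The first principal component held 22.8% of the variance and gave these 4 libraries positive scores and the other 5 negative ones. Each comparison was repeated with a striatal marker score as a covariate and without these 4 libraries, both chosen after seeing the data. The latter leaves 1 sham, 3 injured saline and 1 R-HNK library, so the spread comes from the injured saline libraries alone.

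The first comparison asks how nerve injury changed the prelimbic cortex of saline-treated mice. Genes that neurons switch on when they fire were higher in injured saline mice. Trib1, a pseudokinase that directs proteins to degradation, measured 19.9 ± 1.79 CPM in sham and 55.3 ± 5.05 CPM in injured saline mice, a log2 fold change of 1.48 ± 0.10 (SE, adjusted p = 3.18e-05). Egr2, a zinc finger transcription factor induced by activity, rose from 7.52 ± 1.69 to 23.6 ± 0.394 CPM (1.65 ± 0.16, adjusted p = 0.000389). Fos, a subunit of the AP-1 transcription factor, rose from 33.4 ± 8.20 to 84.4 ± 5.83 CPM (1.34 ± 0.16, adjusted p = 0.00484). Arc, which controls the removal of AMPA receptors from synapses, went from 140.0 ± 41.5 to 530.4 ± 80.7 CPM (1.92 ± 0.24, adjusted p = 0.0151). In the other direction, Igfbpl1, a gene of immature neurons, went from 7.50 ± 3.41 to 0.900 ± 0.197 CPM (-3.05 ± 0.37, adjusted p = 0.00302). Pbx3, a homeodomain transcription factor, fell from 21.2 ± 2.72 to 6.09 ± 0.947 CPM (-1.80 ± 0.18, adjusted p = 0.000499).

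Of 21765 genes tested, 233 changed between injured saline and sham mice, 112 higher and 121 lower, and 3611 had an unadjusted p under 0.05. The other highest fold changes by the naming rule were those of Depp1, Klf10, Gadd45a, Nr4a1, Tnfrsf25 and Csrnp1, from 2.03 down to 1.28. Nr4a1, an orphan nuclear receptor, rose from 88.0 ± 14.7 to 235 ± 3.71 CPM, and Gadd45a, a stress-induced growth arrest gene, from 6.05 ± 0.614 to 16.9 ± 2.86 CPM. The other lowest fold changes were those of Scgn, Gpr101, Pipox, Sp8, Cdca7, Zic1, Hydin and Bmp6, from -3.37 up to -1.64. Scgn, a calcium-binding protein of some interneurons, fell from 3.08 ± 0.923 to 0.297 ± 0.165 CPM, and Sp8, a transcription factor of developing interneurons, from 13.3 ± 0.380 to 3.30 ± 1.43 CPM. On the GRCm38 (mm10) assembly Trib1 lies on chromosome 15 from 59648350 to 59657099, Arc on chromosome 15 from 74669083 to 74672570, Fos on chromosome 12 from 85473890 to 85477273 and Igfbpl1 on chromosome 4 from 45809468 to 45826923. The count of 233 was 1170, 62 and 86 without sham replicates 1, 2 and 3, 134, 63 and 60 without injured saline replicates 1, 2 and 3, and 133 and 361 without R-HNK replicates 1 and 2. Of the 50 named genes that passed, 21 passed in all 9 fits that left out 1 library, 25 with the striatal score as a covariate and 21 without the 4 libraries raised in striatal markers. With the striatal score as a covariate 78 genes passed, 60 of them among the 233, and without the 4 libraries raised in striatal markers 86 passed, 39 of them among the 233. Arc missed the threshold without sham replicate 2 (adjusted p = 0.0825), injured saline replicate 2 (0.0588) or injured saline replicate 3 (0.068), within a range of 7.17e-11 to 0.0825 over all settings tried. Scgn and Sp8 missed it without sham replicate 2 and without injured saline replicates 2 or 3, and Sp8 also without sham replicate 3.

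Activity-regulated immediate early genes rose as a group in injured saline mice. Of 34 measured members 22 rose and 12 did not pass, and 28 were higher when adjusted over the list alone (median 0.99, camera adjusted p = 8.44e-34, estimated-correlation adjusted p = 0.0333). Examples besides Trib1, Egr2 and Fos were Dusp6, a phosphatase that turns off ERK signalling (53.4 ± 6.64 to 113 ± 6.56 CPM, 1.08 ± 0.09), Egr4 (60.4 ± 5.99 to 122 ± 5.05 CPM, 1.01 ± 0.09) and Nr4a3 (29.9 ± 1.28 to 70.1 ± 7.19 CPM, 1.23 ± 0.11). The number of members called was 14 without sham replicate 2 and 14 without injured saline replicate 3. It was 23 with the striatal score as a covariate and 22 without the 4 libraries raised in striatal markers. Of 30 heat shock and protein folding genes 2 rose and 28 did not pass, with 13 higher when adjusted over the list alone (median 0.19, camera adjusted p = 1.83e-08, estimated-correlation adjusted p = 0.245). The 2 were the HSP40 co-chaperones Dnajb5 (0.72 ± 0.11) and Dnajb1 (0.40 ± 0.08). Of 29 glucocorticoid-responsive genes Per1 (0.90 ± 0.08) and Dusp1 (1.18 ± 0.17) rose and 27 did not pass, with 9 higher and 2 lower when adjusted over the list alone (median 0.20, camera adjusted p = 0.000222, estimated-correlation adjusted p = 0.204). Both are also induced by neuronal activity. Dnajb1 and Dusp1 missed the threshold when sham replicate 2 or injured saline replicate 1 or 3 was left out. Dnajb5 and Dnajb1 missed it with the striatal covariate and without the 4 libraries, while Per1 and Dusp1 passed in both. Of 19 clock genes Per1 alone rose, with 4 higher when adjusted over the list alone (median 0.09, camera adjusted p = 0.00624, estimated-correlation adjusted p = 0.245). The clock call was lost with the striatal covariate and without the 4 libraries. The 62 mitochondrial respiratory chain subunits also rose as a group (median 0.13, camera adjusted p = 2.71e-08, estimated-correlation adjusted p = 0.376), with no member passing singly in edgeR.

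**Figure D1:**
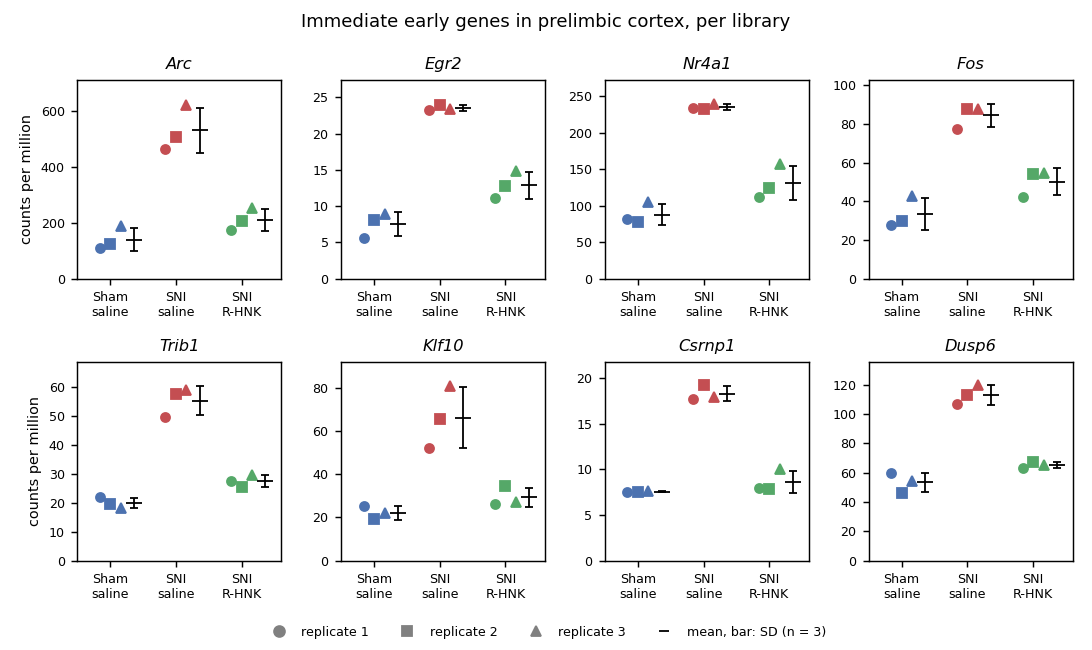
CPM of 8 activity-regulated immediate early genes in each library, with the mean and SD of each group. Arc lay between 465 and 620.4 CPM in the injured saline libraries and between 108 and 187 CPM in the sham libraries.

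Genes of the AMPA receptor, the subject of the series title, did not pass the test as a group. Of 28 measured members Nptx1, a pentraxin that clusters AMPA receptors, rose from 443 ± 68.3 to 618 ± 19.0 CPM (0.48 ± 0.10, adjusted p = 0.0455). Cacng5, an auxiliary subunit, fell from 23.4 ± 1.57 to 8.52 ± 2.12 CPM (-1.46 ± 0.21, adjusted p = 0.00991). The other 26 did not pass. Adjusted over the list alone, 1 was higher and 2 were lower. The list's median was -0.01 and its mean -0.04, while camera's direction was up (adjusted p = 0.743), and down without a pass with the striatal covariate or without the 4 libraries raised in striatal markers. The pore-forming subunits Gria1, Gria2, Gria3 and Gria4 had fold changes of -0.22 ± 0.09, -0.09 ± 0.07, 0.13 ± 0.08 and 0.16 ± 0.12, with adjusted p = 0.25, 0.551, 0.451 and 0.545. Gria1 measured 457 ± 46.3 CPM in sham and 391 ± 26.2 CPM in injured saline mice. Dlg4, which encodes the scaffold PSD-95, measured 908 ± 32.9 and 922 ± 79.5 CPM (0.02 ± 0.07, adjusted p = 0.916). Cacng5 missed the threshold without sham replicate 2 or injured saline replicate 3, and Nptx1 passed in 2 of the 9 fits that left out 1 library, those without sham replicate 1 or R-HNK replicate 2. Nptx1 also missed it with the striatal covariate and without the 4 libraries, and Cacng5 passed in both. RNA levels do not measure where a receptor sits in the cell.

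Other neuronal groups moved by small amounts. The 31 synaptic vesicle release genes rose as a group, with 5 higher when adjusted over the list alone (median 0.17, camera adjusted p = 1.76e-05, estimated-correlation adjusted p = 0.421). This call was lost with the striatal covariate and without the 4 libraries raised in striatal markers. Among 21 NMDA, kainate and metabotropic glutamate receptor genes Grm4 fell (-0.51 ± 0.10), and the list did not pass (adjusted p = 0.122). Slc6a11, a GABA transporter of astrocytes, fell (-0.48 ± 0.09) in a GABA list that did not pass (adjusted p = 0.535). Cacna1c, an L-type calcium channel, fell (-0.39 ± 0.08) in an ion channel list that did not pass (adjusted p = 0.711). Sstr2, a somatostatin receptor, rose (1.01 ± 0.16) and Tacr1, the substance P receptor, fell (-1.53 ± 0.27) in the neuropeptide list (adjusted p = 0.622). Adrb1, a beta adrenergic receptor, rose (0.58 ± 0.09) in the monoamine and acetylcholine receptor list (adjusted p = 0.214). C4b, a complement component, fell (-1.55 ± 0.29) in the cytokine and innate immune list (adjusted p = 0.954), though its reads are hard to part from those of its close paralog C4a. When 1 library was left out, Adrb1 missed the threshold only without sham replicate 2. Grm4, Slc6a11, Cacna1c, Sstr2, Tacr1 and C4b each missed it when sham replicate 2 or 3 or injured saline replicate 2 or 3 was left out. All 7 of these genes missed it with the striatal covariate, and all but C4b without the 4 libraries. The lists of postsynaptic density genes, BDNF and mTOR signalling and cytosolic ribosomal proteins had adjusted p = 0.622, 0.358 and 0.743. Ribosomal proteins passed as higher with the striatal covariate, and ion channels passed as lower with the covariate only. Without the 4 libraries ribosomal proteins had a median of 0.12, set against sham replicate 1 alone. Median, mean and camera's direction differed in sign for the neuropeptide, monoamine, cytokine and ribosomal lists. Interferon-stimulated genes were lower as a group (median -0.19, camera adjusted p = 0.0452, estimated-correlation adjusted p = 0.582). This call was lost with the striatal covariate (adjusted p = 0.591) and without the 4 libraries raised in striatal markers (0.988), within a range of 0.00725 to 0.988 over all settings tried.

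Markers of cell types also moved. The 10 excitatory neuron markers rose as a group (median 0.35, camera adjusted p = 1.76e-05, estimated-correlation adjusted p = 0.421), with 1 member passing, Neurod6 (73.7 ± 12.7 to 119 ± 3.93 CPM, 0.70 ± 0.11), and 5 higher when adjusted over the list alone. Deep layer markers Fezf2 (0.87 ± 0.14) and Rprm (0.60 ± 0.09) rose, while neither the deep layer nor the upper layer list passed (adjusted p = 0.134 and 0.164). Of 13 inhibitory interneuron markers Dlx1, Dlx5, Reln and Adarb2 fell and 9 did not pass, with 2 higher and 7 lower when adjusted over the list alone (median -0.38, camera adjusted p = 0.0452, estimated-correlation adjusted p = 0.421). Dlx1, a homeodomain factor of interneurons, fell from 71.3 ± 1.82 to 44.5 ± 3.71 CPM (-0.68 ± 0.08). The 15 striatal markers were lower as a group (median -2.16, camera adjusted p = 7.71e-05, estimated-correlation adjusted p = 0.469), with no member passing singly. Of 15 meningeal and perivascular fibroblast markers Igf2 (-1.01 ± 0.16), Fmod (-0.95 ± 0.18) and Col1a1 (-1.02 ± 0.21) fell and 12 did not pass, with 8 lower when adjusted over the list alone (median -0.98, camera adjusted p = 7.28e-07, estimated-correlation adjusted p = 0.245). Astrocyte markers (median -0.15, camera adjusted p = 0.00584, estimated-correlation adjusted p = 0.469) were lower as a group, with Slc4a4, a bicarbonate transporter, the 1 member called (-0.57 ± 0.11). Lists of choroid plexus and ependyma (median -0.81, camera adjusted p = 0.000266, estimated-correlation adjusted p = 0.204) and oligodendrocyte precursors (median -0.35, camera adjusted p = 0.00365, estimated-correlation adjusted p = 0.421) were lower as well. So were microglia (median -0.15, camera adjusted p = 0.0165, estimated-correlation adjusted p = 0.545) and blood cells (median -0.50, camera adjusted p = 0.0171, estimated-correlation adjusted p = 0.436). With the striatal covariate the calls of excitatory neurons, astrocytes, oligodendrocyte precursors, microglia and blood cells were lost. Without the 4 libraries these 5 were lost too, as were interneurons and choroid plexus. Fibroblast markers passed with the covariate, and deep layer markers passed as higher and upper layer markers as lower. Without the 4 libraries these medians were -1.21, 0.20 and -0.31, set against sham replicate 1 alone. Scored by mean log2 CPM relative to the 9 libraries, sham replicate 1 was highest for fibroblasts (0.83) and upper layers (0.29). It was lowest for deep layers (-0.16). Sham replicates 2 and 3 scored -0.17 and 0.49, 0.03 and -0.06, and -0.03 and -0.01 in that order. Both settings were built from the striatal markers, so they do not test that list. Among these genes Dlx1 passed in all 9 fits that left out 1 library. Neurod6, Fezf2, Rprm, Dlx5, Reln, Adarb2, Igf2, Fmod, Col1a1 and Slc4a4 each missed the threshold without injured saline replicate 2, and all of these but Igf2 without sham replicate 2. With the striatal covariate Dlx1, Neurod6 and Fmod passed, and without the 4 libraries Dlx1 and Igf2. Endothelial and pericyte lists did not pass (adjusted p = 0.622 and 0.0886). Endothelial markers turned from lower to higher and passed with the striatal covariate. Without the 4 libraries they were higher too (median 0.21), set against sham replicate 1 alone. That library scored lowest of the 9 (-0.29, against 0.20 and 0.16 in sham replicates 2 and 3).

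Oligodendrocyte and myelin markers were lower in injured saline mice with all 9 libraries (median -0.41, camera adjusted p = 0.0206, estimated-correlation adjusted p = 0.661). They were higher with the striatal score as a covariate (camera adjusted p = 1.53e-05), within a range of 1.03e-05 to 0.661 over all settings tried. The covariate also moved the striatal markers past 0, to a median of 0.12. Without the 4 libraries raised in striatal markers the oligodendrocyte median was 0.31, set against sham replicate 1 alone. Its mean log2 CPM of these markers, relative to all 9 libraries, was -0.46. The injured saline replicates had -0.54, -0.11 and 0.03, so injured saline replicate 1 lay below sham replicate 1. Of the 31 lists 17 passed, 7 up and 10 down, in this comparison. With an estimated correlation only the immediate early genes passed, and with fry, which tests whether a list's genes move on balance one way, 7 lists passed.

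The second comparison asks how R-HNK changed the prelimbic cortex of injured mice. Some genes of the first comparison moved the other way. Trib1 fell from 55.3 ± 5.05 to 27.6 ± 2.04 CPM (-1.0 ± 0.10, adjusted p = 0.00221), Dusp6 from 113 ± 6.56 to 65.4 ± 1.98 CPM (-0.79 ± 0.09, adjusted p = 0.00335) and Csrnp1, a nuclear protein induced by activity, from 18.3 ± 0.803 to 8.64 ± 1.21 CPM (-1.08 ± 0.12, adjusted p = 0.00335). Spry4, an inhibitor of growth factor signalling, fell from 22.8 ± 1.67 to 12.7 ± 0.196 CPM (-0.84 ± 0.09, adjusted p = 0.00335). Sp9, a transcription factor of developing interneurons, rose from 7.11 ± 0.819 to 15.9 ± 1.94 CPM (1.16 ± 0.14, adjusted p = 0.00622), and Igfbpl1 rose from 0.900 ± 0.197 to 5.49 ± 1.63 CPM (2.60 ± 0.36, adjusted p = 0.0209).

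Of the 21765 genes 26 changed between R-HNK and injured saline mice, 8 higher and 18 lower, and 1625 had an unadjusted p under 0.05. The 8 higher genes were Igfbpl1, Cdca7, Pbx3, Sp9, Pcdhgb5, Dlx2, Pax6 and Dlx1, with fold changes from 2.60 down to 0.55. Dlx2 and Pax6, homeodomain factors that specify interneurons and olfactory bulb neurons, rose from 6.58 ± 1.12 to 12.9 ± 1.19 and from 7.66 ± 0.830 to 12.8 ± 1.42 CPM. Pcdhgb5 shares its last exons with the other genes of its protocadherin cluster, so its reads are not surely its own. Sp9 lies on chromosome 2 from 73271925 to 73284706 and Dlx2 on chromosome 2 from 71543408 to 71546754. The lower genes named by the rule were Klf10, Gadd45a, Csrnp1, Trib1, Nr4a1, Spry4, Nr4a3, Dusp6, Sertad1 and Stk40, from -1.18 to -0.69. The count of 26 was 56 without sham replicate 1, 8 and 7 without injured saline replicates 2 and 3, and 10 and 15 without R-HNK replicates 1 and 3. Of 20 named genes that passed, Trib1, Csrnp1, Dusp6, Spry4, Stk40 and Sp9 passed in all 9 fits that left out 1 library. With the striatal covariate 19 of the 20 passed, and 11 without the 4 libraries. Igfbpl1 missed the threshold when any injured saline replicate or R-HNK replicate 1 or 3 was left out. Dlx2 and Pax6 each passed in only 2 of the 9 fits that left out 1 library. Pax6 also missed the threshold with the striatal covariate (edgeR adjusted p = 0.0635). With the striatal score as a covariate 38 genes passed, 24 of them among the 26, and without the 4 libraries raised in striatal markers 37 passed, 12 of them among the 26.

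Of the 34 immediate early genes 8 fell and 26 did not pass, with 24 lower when adjusted over the list alone (median -0.60, camera adjusted p = 7.78e-26, estimated-correlation adjusted p = 0.0668), and fry gave adjusted p = 0.00721. Egr4 fell from 122 ± 5.05 to 79.5 ± 6.67 CPM (-0.62 ± 0.08). Arc measured 530.4 ± 80.7 CPM in injured saline and 211 ± 38.7 CPM in R-HNK mice (-1.33 ± 0.23) and did not pass (adjusted p = 0.213). The number of members called was 13 without sham replicate 3, and 3 without injured saline replicate 2, injured saline replicate 3 or R-HNK replicate 1. It was 13 with the striatal covariate, 18 in DESeq2, 16 with the 2 compared groups alone and 15 in limma-voom with quality weights, all lower. Clock genes were lower as a group, with Per1 the 1 member called (145 ± 9.48 to 93.6 ± 8.19 CPM) and 2 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.000307, estimated-correlation adjusted p = 0.206). Glucocorticoid-responsive genes were lower too, again with Per1 the 1 member called and 4 lower when adjusted over the list alone (median -0.07, camera adjusted p = 0.0308, estimated-correlation adjusted p = 0.55). Mitochondrial (median -0.08, camera adjusted p = 1.41e-05, estimated-correlation adjusted p = 0.564) and vesicle release lists (median -0.11, camera adjusted p = 0.000117, estimated-correlation adjusted p = 0.573) were lower as groups. So were heat shock (median -0.08, camera adjusted p = 0.000568, estimated-correlation adjusted p = 0.564) and excitatory neuron lists (median -0.22, camera adjusted p = 0.00124, estimated-correlation adjusted p = 0.573). No member of these 4 lists passed singly in edgeR. Without the 4 libraries the clock, mitochondrial and excitatory neuron calls were lost, and all 7 lower lists passed with the striatal covariate.

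Markers of other tissues were higher in R-HNK than in injured saline mice. The 9 blood cell markers were higher as a group, with 5 higher when adjusted over the list alone (median 0.96, camera adjusted p = 4.04e-07, estimated-correlation adjusted p = 0.206). Hba-a1, a haemoglobin chain whose reads are shared with its near-identical copy Hba-a2, measured 103 ± 25.0 CPM in injured saline and 205 ± 21.3 CPM in R-HNK mice (0.99 ± 0.17, adjusted p = 0.127). Striatal markers were higher as a group (median 1.42, camera adjusted p = 0.000781, estimated-correlation adjusted p = 0.653). So were meningeal fibroblasts (median 0.35, camera adjusted p = 0.000801, estimated-correlation adjusted p = 0.564) and choroid plexus (median 0.63, camera adjusted p = 0.0208, estimated-correlation adjusted p = 0.55). Ribosomal proteins were higher (median 0.06, camera adjusted p = 0.0091, estimated-correlation adjusted p = 0.731). Oligodendrocyte precursors (median 0.18, camera adjusted p = 0.0091, estimated-correlation adjusted p = 0.573) and microglia (median 0.10, camera adjusted p = 0.0366, estimated-correlation adjusted p = 0.653) were higher as well. The ribosomal, precursor and microglia calls were lost with the striatal covariate and without the 4 libraries. The choroid plexus call was lost without the 4 libraries. Interneuron markers did not pass as a list (adjusted p = 0.116), while Dlx1 rose from 44.5 ± 3.71 to 65.2 ± 5.95 CPM (0.55 ± 0.08). Of the 31 lists 14 passed, 7 up and 7 down. With an estimated correlation 0 passed in camera, where 3 had an unadjusted p under 0.05, and 3 passed in fry.

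The AMPA receptor list did not pass between R-HNK and injured saline mice (median -0.01, mean 0.01, direction down, camera adjusted p = 0.607). Gria1 measured 391 ± 26.2 CPM in injured saline and 443 ± 47.2 CPM in R-HNK mice (0.18 ± 0.09, adjusted p = 0.691). Gria2, Gria3 and Gria4 had fold changes of 0.00 ± 0.07, -0.11 ± 0.08 and -0.17 ± 0.12 (adjusted p = 0.993, 0.767 and 0.767), and Dlg4 -0.03 ± 0.07 (adjusted p = 0.937). The largest shift among the 28 members by p was that of Cacng5, 8.52 ± 2.12 CPM in injured saline and 15.0 ± 4.31 CPM in R-HNK mice (0.81 ± 0.21, adjusted p = 0.359). Bdnf, the growth factor linked to the action of ketamine, measured 36.1 ± 1.74 and 25.9 ± 1.70 CPM (-0.48 ± 0.14, adjusted p = 0.433), in a BDNF and mTOR signalling list that did not pass (adjusted p = 0.371). The other lists had adjusted p from 0.061 for oligodendrocytes to 0.945 for interferon-stimulated genes. Without the 4 libraries, which leaves R-HNK replicate 2 alone, both of these turned to lower (medians -0.24 and -0.27). Deep layers had a median of -0.18 there and interneurons 0.15. Median, mean and camera's direction differed in sign for the neuropeptide, monoamine and deep layer lists.

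Genes called with nerve injury were followed into the R-HNK mice. Of the 112 genes higher in injured saline mice 111 had a fold change below 0 in R-HNK against injured saline mice, with a median of -0.40 after a median of 0.67 with injury. All 121 genes lower in injured saline mice had a fold change above 0, with a median of 0.51 after -0.86. Genes picked for high or low injured saline libraries tend to run back against the same libraries. This was simulated in 20 data sets in which the 233 genes changed with injury by their fitted amounts and R-HNK changed nothing. There 56.2% of the genes called higher (46.2% to 63.0%) and 58.9% of those called lower (50.7% to 65.1%) had the opposite sign. Observed were 99.1% and 100%. The simulated medians were -0.02 and 0.04. Genes were drawn independently, so differences in tissue between libraries are not in these simulations. Both injured groups carried the injury change in them. A difference in the injured saline libraries alone, such as handling, time of day or dissected tissue, would also run back in R-HNK mice. The simulations cannot part this from an effect of R-HNK, and no sham mice were given R-HNK. Against sham mice the 2 sets kept medians of 0.26 and -0.28 in R-HNK mice. In 25 genes both changes passed with opposite signs, 17 of them higher and then lower and 8 lower and then higher, where independent lists of these sizes would share 0.0926 and 0.0445 genes. These lists share the injured saline libraries and are not independent, so part of that excess may come from the shared controls. The simulations with injury alone gave 0.3 such genes on average and at most 3. The 10 with the largest such changes were Igfbpl1, Cdca7, Pbx3, Klf10, Sp9, Gadd45a, Csrnp1, Pcdhgb5, Trib1 and Dlx2. Sp9 measured 19.1 ± 2.78 CPM in sham, 7.11 ± 0.819 in injured saline and 15.9 ± 1.94 in R-HNK mice, and Csrnp1 7.55 ± 0.0473, 18.3 ± 0.803 and 8.64 ± 1.21 CPM.

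Both changes use the injured saline libraries, which alone makes them run opposite. Across genes, which are not independent replicates, the fold changes had a correlation of -0.73, against -0.50 (-0.53 to -0.46) in 20 simulated data sets with no change that shared these libraries. Their covariance was -0.277 against a simulated -0.0974, a difference of -0.179, and the share of genes with opposite signs was 77.5% against 66.7%. Without the 4 libraries raised in striatal markers the correlation was -0.23, no more negative than the -0.24 (-0.28 to -0.22) of 20 simulated data sets with no change and these 5 libraries. The covariance there was -0.352 against a simulated -0.145. Opposite signs were 60.7% against 58.1% (57.5% to 58.6%). The count of 25 was 54 without sham replicate 1, 8 and 7 without injured saline replicates 2 and 3, and 10 and 14 without R-HNK replicates 1 and 3. With the striatal covariate 29 genes passed, 21 of them among the 25. Without the 4 libraries 1 sham and 1 R-HNK library remain, so a difference of a single mouse also makes genes run back. Genes were drawn independently in the simulations, so such differences shared by many genes are not in them. Reversed genes and the covariance in that setting cannot part group from mouse.

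**Figure D2:**
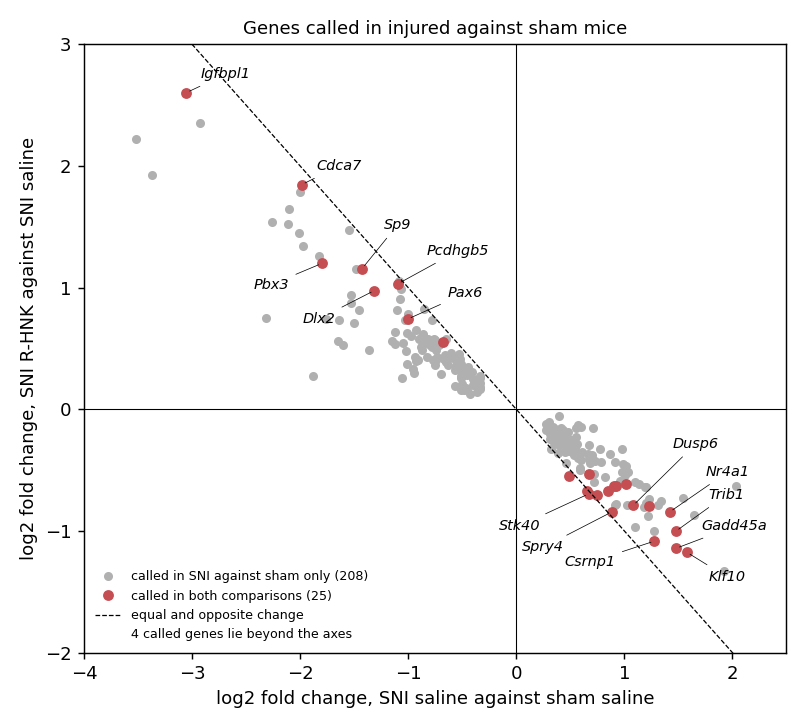
Log2 fold change of R-HNK against injured saline mice (vertical) and of injured saline against sham mice (horizontal) for the 233 genes that changed with injury; red points mark the 25 genes that passed in both, and 4 genes lie beyond the axes. The points shown fall in the upper left and lower right parts of the plot, and Gm6344, which had the same sign in both comparisons, is 1 of the 4.

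The third comparison asks how far injured mice given R-HNK still differed from sham mice. In edgeR 1 of 21765 genes passed, Gm6344, a processed pseudogene on chromosome 13 from 55085777 to 55086259. The naming rule leaves it out, and it is named here after its values were seen. It measured 0, 0.0174 and 0 CPM in sham, 0.974, 0.317 and 0.699 in injured saline and 2.03, 2.2 and 1.12 in R-HNK mice, and reads of a processed pseudogene may belong to its parent gene. The rule also leaves out other genes annotated as pseudogenes, Pcdhgb8 among them. The genes with the smallest unadjusted p among those the rule allows did not pass. Egr2 measured 7.52 ± 1.69 CPM in sham and 12.9 ± 1.87 CPM in R-HNK mice (0.78 ± 0.16, adjusted p = 0.93) and Trib1 19.9 ± 1.79 and 27.6 ± 2.04 CPM (0.47 ± 0.10, adjusted p = 0.93). Ikzf2, a zinc finger transcription factor, measured 3.94 ± 0.471 and 1.09 ± 0.606 CPM (-1.86 ± 0.34, adjusted p = 0.843). At an unadjusted p under 0.05 there were 769 genes, 3.53% of those tested, below the share of 0.05 that no difference would give. Both groups mix libraries raised and not raised in striatal markers, which widens the spread within each group. The low share thus does not show that R-HNK mice match sham mice. The count of genes that passed was 11 without sham replicate 1, 2 and 3 without sham replicates 2 and 3, 2 without R-HNK replicate 2 and 2 without R-HNK replicate 3. DESeq2 called 10 genes and limma-voom with quality weights called 0. The count was 25 without the 4 libraries, but this sets 1 R-HNK against 1 sham library and cannot part group from mouse.

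Immediate early genes were higher as a group in R-HNK than in sham mice (median 0.39, camera adjusted p = 1.66e-21, estimated-correlation adjusted p = 0.105), with 15 of 34 higher when adjusted over the list alone and no member passing over all genes in edgeR, against 4 in DESeq2. Ptgs2, a prostaglandin synthase induced by activity, measured 10.2 ± 0.644 CPM in sham and 15.0 ± 0.995 CPM in R-HNK mice (0.55 ± 0.11, adjusted p = 0.93), and Arc 140.0 ± 41.5 and 211 ± 38.7 CPM (0.59 ± 0.23, adjusted p = 1). Heat shock (median 0.10, camera adjusted p = 1.41e-05, estimated-correlation adjusted p = 0.453) and ribosomal lists (median 0.05, camera adjusted p = 0.000459, estimated-correlation adjusted p = 0.741) were higher as groups. So were blood cells (median 0.48, camera adjusted p = 0.000459, estimated-correlation adjusted p = 0.453) and glucocorticoid-responsive genes (median 0.10, camera adjusted p = 0.00434, estimated-correlation adjusted p = 0.453). Mitochondrial subunits were higher too (median 0.04, camera adjusted p = 0.00589, estimated-correlation adjusted p = 0.655). Excitatory neurons (median 0.14, camera adjusted p = 0.0046, estimated-correlation adjusted p = 0.641) and deep layers (median 0.16, camera adjusted p = 0.0216, estimated-correlation adjusted p = 0.641) were higher as well, the latter with 2 higher when adjusted over the list alone. Meningeal fibroblasts (median -0.46, camera adjusted p = 0.000112, estimated-correlation adjusted p = 0.453) and choroid plexus (median -0.57, camera adjusted p = 0.0253, estimated-correlation adjusted p = 0.453) were lower, as were astrocytes (median -0.13, camera adjusted p = 0.00482, estimated-correlation adjusted p = 0.641). Interferon-stimulated genes were lower too (median -0.18, camera adjusted p = 0.00589, estimated-correlation adjusted p = 0.641). GABA genes (median -0.07, camera adjusted p = 0.0199, estimated-correlation adjusted p = 0.641) and ion channels (median -0.06, camera adjusted p = 0.0308, estimated-correlation adjusted p = 0.647) were also lower. With the striatal covariate the calls of interferon-stimulated genes, mitochondrial subunits, excitatory neurons, astrocytes and choroid plexus were lost. Without the 4 libraries, with 1 library per group, those of GABA genes, ion channels, excitatory neurons, deep layers, astrocytes and choroid plexus were lost. Endothelial markers passed as higher with the covariate and had a median of 0.18 without the 4 libraries. With the covariate alone cytokine genes passed as higher and postsynaptic density genes and upper layers as lower. Oligodendrocytes turned from lower to higher and passed with it (median 0.28, against 0.05 without the 4 libraries). That turn may come from the covariate, which also moved the striatal markers it was built from past 0, to a median of 0.39. Striatal markers did not pass (median -0.78, camera adjusted p = 0.0569), though they turned and passed as higher with the covariate built from them. Nor did the AMPA receptor list (camera adjusted p = 0.782), in which Gria1 measured 457 ± 46.3 and 443 ± 47.2 CPM (-0.04 ± 0.09). Of the 31 lists 14 passed, 8 up and 6 down. With an estimated correlation 0 passed in camera (2 at an unadjusted p under 0.05) and 0 passed in fry (2 at an unadjusted p under 0.05). Median, mean and direction differed in sign for the neuropeptide, monoamine, cytokine, clock, endothelial and pericyte lists, and the lists that did not pass had adjusted p of at least 0.0569.

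A test for any difference among the 3 groups called 83 genes, with 2363 at an unadjusted p under 0.05. The count was 528 without sham replicate 1, 39 and 55 without sham replicates 2 and 3, 47, 21 and 23 without injured saline replicates 1, 2 and 3, and 136 without R-HNK replicate 2. Trib1 had an adjusted p of 7.01e-05 in this test, Sp9 of 0.00102 and Igfbpl1 of 0.00995. Gria1 had 0.515 and did not pass.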

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

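The filter at a mean log2 CPM of 0, the halved counts, the striatal covariate and the omission of 4 libraries were chosen after the result was seen; the other settings were planned. The scalings by relative log expression and upper quartile kept 229 and 210 of the 233 genes of injured saline against sham mice. Without a filter 370 genes passed there and 128 among 3 groups. DESeq2 called 1185, 140, 10, 679 and 116 genes for injured saline against sham, R-HNK against injured saline, R-HNK against sham, any difference among groups, and reversed genes. Limma-voom with quality weights called 1135, 49, 0, 420 and 45 in that order. Beside the 0, edgeR had 769 genes at an unadjusted p under 0.05, 3.53% of those tested and no more than chance would give. Striatal markers vary within both of these groups, which widens the spread, so this share does not show that the groups match. DESeq2 kept 230 and limma-voom 232 of the 233. With replicate number as a block 16 genes passed for R-HNK against injured saline mice, 2 for R-HNK against sham mice and 43 among 3 groups, with 16 reversed; numbers did not pair the libraries, since same-number correlations ran from -0.104 to 0.0917. With the 2 compared groups alone 53 genes passed for R-HNK against injured saline mice. With the higher filter 0 genes passed in edgeR for R-HNK against sham mice, since that filter removes Gm6344, the 1 gene called. The striatal covariate gave 78 genes for injured saline against sham mice, 2 for R-HNK against sham mice and 43 among groups; omission of the 4 libraries, which leaves 1 sham and 1 R-HNK library assumed to vary like the others, gave 86 for injured saline against sham and 25 for R-HNK against sham mice. Leaving out 1 library gave 60 to 1170 genes for injured saline against sham, 7 to 56 for R-HNK against injured saline, 1 to 11 for R-HNK against sham, 21 to 528 among groups and 7 to 54 reversed. Lists numbered 11 to 19, 10 to 16 and 8 to 15 in those fits; of 17, 14 and 14 called lists, 11, 7 and 3 passed in all 9. An estimated correlation gave 1, 0 and 0 lists, with 6, 3 and 2 at an unadjusted p under 0.05, fry gave 7, 3 and 0, and omission of the 4 libraries gave 10 for injured saline against sham and 9 for R-HNK against sham mice. Some lists that had passed turned direction with the striatal covariate or without the 4 libraries. For injured saline against sham mice these were interferon-stimulated genes (adjusted p = 0.591 and 0.988, all alternatives 0.00725 to 0.988), oligodendrocytes (1.53e-05 and 0.0127, 1.03e-05 to 0.661), microglia (0.717 and 0.833, 0.000791 to 0.833) and, with the covariate, striatal markers (0.421, 4.83e-10 to 0.988). Without the 4 libraries striatal markers (0.441, 2.06e-06 to 0.653) and microglia (0.979, 0.0106 to 0.979) turned for R-HNK against injured saline mice, and GABA genes (0.705, 0.0015 to 0.705) and excitatory neurons (0.855, 1.63e-07 to 0.855) for R-HNK against sham mice. Both settings were built from the striatal markers and do not test that list. Some lists that had not passed turned and passed with the covariate. They were endothelial cells for injured saline against sham mice, and oligodendrocytes and striatal markers for R-HNK against sham mice. The covariate moved the striatal markers past 0 there (median 0.39), so the turn of oligodendrocytes may come from it. Without the 4 libraries endothelial cells turned for injured saline against sham mice (median 0.21), set against 1 sham library. Oligodendrocytes (-0.24) and interferon-stimulated genes (-0.27) turned for R-HNK against injured saline mice, with 1 R-HNK library. Others turned without a pass. No named gene that passed turned direction under any of these settings, though some that did not pass did. Apart from the higher filter, the cause was not tested.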

Other observations

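The neuroblast list, the tests of the striatal markers across libraries and of striatal tissue as the whole cause, and the settings with a striatal covariate or without 4 libraries were chosen after the result was seen; the other tests were written down before their results. Genes of migrating neuroblasts and their progenitors followed the course of Igfbpl1 and Sp9 as a group, though not each one, and 2 of them, Dlx5 and Etv1, are also in lists of the report. Of 35 such genes 7 fell in injured saline against sham mice and 28 did not pass, 30 had a negative fold change, and 21 were lower and 2 higher when adjusted over the list alone (median -0.56, camera p = 9.54e-10, p = 0.0149 with an estimated correlation). Dcx, a microtubule protein of migrating neurons, had means of 64.2, 38.3 and 56.1 CPM in sham, injured saline and R-HNK mice, and its fold change with injury was -0.74 ± 0.12 (SE, edgeR adjusted p = 0.0151). Sox4, a transcription factor of immature neurons, had 53.1, 32.4 and 46.7 CPM (-0.71 ± 0.10, adjusted p = 0.00426) and Cd24a, a surface protein of neuroblasts, 11, 5.19 and 10.8 CPM (-1.09 ± 0.22, adjusted p = 0.042). Stmn1, the most abundant member and a gene of many neurons, had 589, 711 and 666 CPM, the other way, and did not pass (adjusted p = 0.0529). In R-HNK against injured saline mice the list was higher (median 0.30, 0.14 with the striatal covariate, camera p = 2.25e-07, p = 0.0289 with an estimated correlation), with 10 members higher when adjusted over the list alone and 0 of 35 passing over all genes in edgeR (15 higher at an unadjusted p under 0.05, 6 called higher in DESeq2 and 2 in limma-voom). Of the 35 genes 31 measured at least 1 CPM in injured saline mice, so cortex itself may express many of them (median -0.56).

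Immediate early genes were higher in injured saline than in sham mice. Other scalings argue against the scaling of libraries as the cause, since 21 of the 22 called genes passed under both, and GC content or gene length does not account for it, since no random list matched on expression, GC content and length had a median as high as 0.99 (highest 0.15), a share of at most 0.01%, the smallest these draws can give. A larger share of excitatory neurons falls short, because their markers rose by 0.37 ± 0.14 (SE) and the immediate early genes by 1.02 ± 0.09. Handling of the animals or tissue around dissection may be the cause, and nerve injury with ongoing prelimbic activity was not tested apart from it. The heat shock list, which some handling would raise, rose too (camera adjusted p = 1.83e-08, adjusted p = 0.245 with an estimated correlation). Handling that only stimulates neurons would leave that list alone, so the test could not have excluded handling. The mitochondrial, vesicle release and excitatory neuron lists rose as well, so the rise is not particular to heat shock genes. Time of day cannot be told apart from nerve injury because dissection times are not given in the sources used here. With Per1 left out of the list, 2 clock genes, Per2 and Bhlhe40, were higher when adjusted over the list alone. With Per1 in it Nfil3 was a further one, which makes the 3 that were written down in advance for this cause. The test thus turns on that choice (median size of change without Per1 0.11). Ciart (0.38 ± 0.13) and Nr1d1 (0.37 ± 0.14) were higher without passing. Dbp (-0.14 ± 0.10), Per3 (-0.09 ± 0.09), Tef (-0.03 ± 0.06) and Clock (-0.04 ± 0.07) did not rise.

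Dlx1, Dlx2, Sp9, Pax6 and Igfbpl1, genes picked after their values were seen, were lower in injured saline than in sham mice. Fewer inhibitory interneurons fall short by the rule written down in advance. The interneuron markers without Dlx1, as a median in each library, differed by -0.22 ± 0.06 (SE) and the 5 genes by -1.29 ± 0.14. The 5 genes were picked after their values were seen, so a wide gap was likely from the start. It cannot exclude fewer interneurons of some kind as a cause of the 5 genes' fall. Less striatal tissue goes with it, since the striatal markers had a median of -2.16 (camera adjusted p = 7.71e-05, adjusted p = 0.469 with an estimated correlation), but not as the whole cause, since all 5 genes passed with the striatal score as a covariate, and without the 4 libraries 3 passed and Dlx2 (-1.31 ± 0.16 to -0.96 ± 0.20) and Pax6 (-1.0 ± 0.12 to -0.92 ± 0.18) missed with fewer libraries and larger SEs, while with the covariate Igfbpl1 went from -3.05 ± 0.37 to -2.18 ± 0.30. Fewer migrating neuroblasts of the rostral migratory stream, which runs beneath the medial prefrontal cortex, in the dissected piece may account for the rest, as the other neuroblast genes had a median of -0.56 (-0.31 with the covariate, and -0.48 in 32 genes without Sp8, Dlx5 and Dlx6, which had been seen). A change in immature neurons within the prelimbic cortex after nerve injury stays open and was not tested.

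Striatal markers were raised in sham replicates 2 and 3 and R-HNK replicates 1 and 3. The 2 sham libraries came from mice given no R-HNK, and whether R-HNK raised the markers in the 2 R-HNK libraries cannot be told apart from a difference in dissection, since no test here separates them. Striatal tissue in the dissected pieces may account for the pattern. Of the 15 markers, 14 were used, those whose excess in sham replicate 2 was larger than their injured saline mean. This choice used the values being tested. The 14 markers kept a similar ratio to sham replicate 2, with medians of 97.3%, 34.2% and 60.9% of its excess in the other 3 libraries. The coefficient of variation between markers was at most 21.9%. Ppp1r1b, the most abundant of those shown per library, measured 80.7, 346 and 330.2 CPM in sham, 85.9, 82.7 and 80.9 in injured saline and 192, 67.3 and 262 in R-HNK mice.

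Other splits of the same libraries were counted for each result. For injured saline against sham mice the real split, with 233 genes, was the 1 split of 10 with as many, and the highest other gave 1 gene. For R-HNK against injured saline mice it was also 1 split of 10, with 26 genes against 2 in the highest other. For R-HNK against sham mice 3 of 10 splits gave as many as the real 1 gene, with 97 in the highest other. In these 3 comparisons the splits are too few for a share under 0.05. Among 3 groups 2 of 100 splits drawn from 280, the real one included, gave as many as the real 83 genes. This share is under 0.05, but it does not show that the groups explain the count. The highest other split gave 272 genes, which points to a structure of the samples. That split set sham replicates 2 and 3 with R-HNK replicate 3, all raised in striatal markers, apart from the rest, as the 97 genes of R-HNK against sham mice came from setting R-HNK replicate 3 with these 2 sham libraries.

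Pcdhgb8, a protocadherin picked after its values were seen, measured 94.9, 40.3 and 79.3 CPM in sham, 29.4, 47.6 and 26.8 in injured saline and 5.56, 3.14 and 5.01 CPM in R-HNK mice, with last exons shared across its cluster (log2 fold change of R-HNK against sham mice -3.96 ± 0.44, edgeR adjusted p = 0.678).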
